A study of Mus musculus with 19 samples.

How the data were processed

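Messenger RNA was measured with oligonucleotide arrays in 19 samples of OT-I cells, CD8 T cells that carry 1 transgenic receptor for an ovalbumin peptide. Per the labels, the cells had been transferred into irradiated or unirradiated B6 hosts and sorted later from lymph node or spleen. The deposited table gave 1 signal intensity per probe set and array, linear and never negative, from 7.68 to 13242.28. The authors' method of making these values is not given in the sources used here. Medians and upper quartiles were nearly equal in all arrays, as for values put on a common scale before deposit. Array medians ranged from 6.03 to 6.12 on the log2 scale after addition of a pseudocount of 16. That range of 0.088 was under the limit of 0.1 that had been set before the data were examined, so the deposited values were used with no further normalisation.

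The irradiated groups were taken from the sample titles and the unirradiated group from the sample descriptions. The groups were unirradiated host (n = 4), irradiated day 5 (n = 8), irradiated day 40 (n = 4) and irradiated day 115 (n = 3). The descriptions of the day-5 samples give day 6 as the day of sorting, the same day as for the unirradiated hosts, and the titles were followed. The descriptions of day-5 arrays 1 and 2 do not name the cell type. The sources used here state neither sex, nor scan date, nor which samples came from separate animals.

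The table held 12488 probe sets. The 66 control probe sets were left out, since the order of their brightness was at odds with their names, and RNA quality was not judged from them. Of the 12422 others, 10833 mapped to 1 gene symbol in the probe table used, 396 to several, and 1193 were not in it. Probe sets whose mean over all arrays was above the 30th percentile, a signal of 26.1, were tested. That left 8695, of which 7739 had 1 symbol, for 6409 genes. Of 8251 genes with a symbol of their own, 2073 had more than 1 such probe set.

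Log2(signal + 16) was fitted with limma 3.58.1 in R 4.3.3. One model held all 19 arrays with the group as the only factor, and variances were moderated with an intensity trend. P-values were adjusted over all tested probe sets of a comparison by the method of Benjamini and Hochberg, and an adjusted p under 0.05 was the threshold for a change. Differences are given as log2 ± standard error and group signals as mean ± SD. The 6 comparisons were each irradiated group against the unirradiated hosts and each pair of irradiated groups.

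Genes were named by a fixed rule. Against unirradiated hosts, it took the 10 largest rises and the 10 largest falls past the threshold, and between irradiated groups 5 of each. A gene qualified if its probe set had exactly 1 symbol and every array of one group lay beyond every array of the other, and it counted by its probe set of highest mean signal. The rule also took up to 4 members per gene list with the largest changes past the threshold, and a fixed panel of 27 CD8 T cell genes. Within the panel, Cd44, Il2ra, Ifng and Klrg1 lay under the filter in every probe set, and Ly6c1, Cd69, Ccnb1, Tcf7 and Tbx21 had no probe set of their own. One panel gene is not reported here. After the data were seen, the same rule was also applied to the fit with the array cluster as a term.

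There were 27 gene lists, 16 of pathways and 11 of cell type markers, all written before the data were examined. The pathway lists were cell cycle and DNA replication, effector molecules, memory CD8 T cell markers, naive and quiescence-linked genes, NK-type receptors, immediate activation genes, interferon-stimulated genes, glycolysis, oxidative phosphorylation, cholesterol and fatty acid synthesis, cytosolic ribosomal proteins, proteasome subunits, apoptosis regulators, p53 targets, cytokine receptors and signalling of T cells, and chemokine receptors and adhesion. The marker lists were CD8 T cell identity, B cells, plasma cells, myeloid cells, neutrophil lineage, erythroid cells, CD4 T cells and regulatory T cells, dendritic cells, stroma and vessels, NK cells, and megakaryocytes. The 25 lists with at least 5 tested genes were tested with camera from limma at its preset correlation between genes of 0.01, and adjusted p is over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. Within a cluster, lists were tested by camera at the preset correlation only. Lists could share genes, so their tests are not independent. Il2rb, Il7r, Il18r1, Il18rap and Socs2 were in both the memory and the cytokine list. Ccl5 and Fasl were in both the memory and the effector list. A list score per array is the mean log2 signal of the tested members minus its mean over the unirradiated hosts.

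The correlations between arrays, computed after the comparisons had been planned, showed 2 clusters that cut across the groups. Average-linkage clustering on 1 minus the Pearson correlation assigned each array to array cluster 1 or 2. The cluster was added as an additive term to the model, and comparisons were also made within 1 cluster where both groups had arrays there. These alternatives, a term for sex by the signal of the Y-linked gene Eif2s3y (limit 100), and the removal of day-115 arrays 2 and 3 were chosen after the data had been seen. That removal leaves 1 day-115 array, so its counts are not given separately.

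The alternatives planned beforehand were quantile normalisation, centring of arrays on their median, pseudocounts of 1 and 64, no filter, a filter at the 50th percentile, eBayes without trend, robust eBayes, a fit of only the groups compared, arrayWeights, a block for replicate number, removal of each array in turn, 1 probe set per gene, day-5 arrays 1 to 4 only, day-5 arrays 5 to 8 only, removal of day-5 arrays 1 and 2, and a split of the unirradiated hosts between comparisons that share them. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.

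The steps were tested on simulated data built with the group sizes and the spread of these arrays, in which 200 of 8695 probe sets had been changed. With no cluster step, a 2-fold change was found in 88.1% to 100% of cases, depending on the comparison, and a 1.5-fold change in 56.7% to 85.1%. With the real cluster step added, the fit on groups alone found 61.2% to 88.1% of 2-fold and 41.8% to 71.6% of 1.5-fold changes, the lowest between day 115 and day 40. In that simulation the fit on groups alone called 1060 unchanged probe sets between day 115 and unirradiated hosts, and the fit with the cluster term called 10. The number of arrays limits the precision of every value.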

Results

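The arrays measured transcripts of OT-I CD8 T cells after transfer into irradiated mice, where few lymphocytes remained and transferred cells could expand, or into unirradiated mice. Cells from 4 unirradiated hosts served as the reference for 8 samples titled day 5, 4 of day 40 and 3 of day 115. Per the labels, the reference was sorted at day 6, and there was no unirradiated group at day 40 or day 115. At those days, the effect of the irradiated host therefore cannot be told apart from that of time after transfer. Array medians lay between 49.6 and 53.7 signal units. Cd8a, the co-receptor that defines the sorted cells, had a signal of 2530 ± 250 in unirradiated hosts (SD, n = 4), 2940 ± 818 at day 5 (n = 8), 2570 ± 515 at day 40 (n = 4) and 2080 ± 188 at day 115 (n = 3). Cd3e, a chain of the T cell receptor complex, stood at 284 ± 6.01, 248 ± 23.2, 226 ± 38.4 and 243 ± 33.3 in the same order. Where a group mean lay near or under the filter level of 26.1, as for Pclaf, Mki67, Cnn3 and Itgae at day 40, Drc1, Gzmm and Alb in unirradiated hosts and Itgae at day 115, the log2 difference depended on the pseudocount and is not an exact size. P-values below measure only the spread between samples, since the labels do not state that samples came from separate animals.

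The arrays formed 2 clusters that cut across the groups. Array cluster 1 held day-5 arrays 1 to 3, day-40 arrays 1 and 2 and all day-115 arrays, and array cluster 2 held day-5 arrays 4 to 8, day-40 arrays 3 and 4 and all unirradiated hosts. The median correlation was 0.974 within a group and a cluster, 0.884 between clusters of the same group, and 0.963 between groups of the same cluster. Among the day-5 arrays, 3611 probe sets differed between the clusters, 2128 higher and 1483 lower in cluster 1. The immediate early gene Fos was higher in cluster 1 by 3.33 ± 0.47 (log2 ± SE), and the small GTPase gene Nras changed by -3.33 there. The day-115 group had no array in cluster 2 and the unirradiated group none in cluster 1, so called genes and call counts are mostly given both on groups alone and with the cluster as a term in the model or within a cluster.

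**Figure D1:**
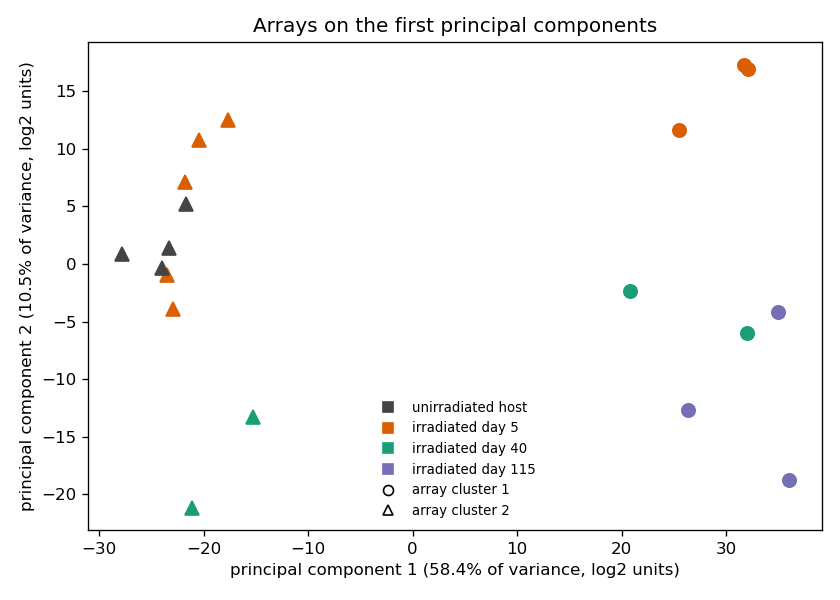
Principal components 1 (58.4% of variance) and 2 (10.5%) of the log2 signals of the 19 arrays, with 1 point per array coloured by group. Circles are arrays of cluster 1 and triangles arrays of cluster 2, which separate along component 1.

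Day 5 against unirradiated hosts asked what had changed early in the irradiated host. The calcium-binding protein gene S100a6 rose from 56.9 ± 20.3 (n = 4) to 507 ± 160 (n = 8), a log2 difference of 2.80 ± 0.27 (adjusted p = 1.16e-05) and of 2.92 with the cluster term. Cxcr3, a chemokine receptor of effector and memory T cells, rose from 160 ± 22 to 560 ± 166, by 1.66 ± 0.20 (adjusted p = 0.000417; 1.58 with the cluster term). The actin-binding calponin gene Cnn3 fell from 145 ± 33.1 to 30.4 ± 7.63, with a log2 difference of -1.79 ± 0.13 (adjusted p = 4.06e-07; -1.75 with the term). Nrip1, a corepressor of nuclear receptors, changed by -1.25 ± 0.18 (adjusted p = 0.00151; -1.08 with the term), and Rflnb, a filamin-binding protein gene, by -1.21 ± 0.17 (adjusted p = 0.00151; -1.02 with the term). These 5 calls held whichever array was left out. Drc1, a gene of the dynein regulatory complex, rose by 1.85 ± 0.24 in its brighter probe set (adjusted p = 0.000882; 2.04 with the term), but the other probe set differed by only 0.12 (adjusted p = 0.477).

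Genes of cell division were higher at day 5. Top2a, a topoisomerase of dividing cells, went from 37.9 ± 6.54 to 226 ± 186, by 1.84 ± 0.39 (adjusted p = 0.0347; 2.20 with the cluster term). The mitotic kinase gene Cdk1 rose by 1.42 ± 0.28 (adjusted p = 0.0247; 1.45 with the term) and the cyclin gene Ccnb2 by 1.03 ± 0.20 (adjusted p = 0.021; 0.91 with the term). Stmn1, a microtubule regulator, rose by 1.94 ± 0.40 in its brighter probe set (adjusted p = 0.0267; 2.17 with the term), which a second probe set did not share (adjusted p = 0.993). The proliferation marker Mki67 stayed outside the threshold at 1.62 ± 0.38 (adjusted p = 0.0503) and passed with the cluster term at 1.88 (adjusted p = 0.00753), but the other probe set of Mki67 differed by only 0.11 (adjusted p = 0.521). Of 70 tested members of the cell cycle list, 6 rose, none fell and 64 did neither over all probe sets, and 31 rose when adjusted over the list alone. The list moved up (camera, adjusted p = 1.66e-19), but adjusted p = 0.313 with an estimated correlation. In the fit with the cluster term, 12 rose (adjusted p = 4.9e-33, or 0.135 with an estimated correlation). Each unirradiated array left out ended the calls of Top2a and Cdk1, removal of unirradiated array 1, 3 or 4 ended those of Ccnb2 and Stmn1, and that of day-5 array 1 ended Stmn1 and Top2a. Top2a was also lost without day-5 array 5 or 6.

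Il7r, Egr1 and Itgae were among the falls at day 5. Il7r, the chain of the receptor through which IL-7 sustains resting T cells, went from 1780 ± 399 to 787 ± 189, with a log2 difference of -1.17 ± 0.25 (adjusted p = 0.0346; -0.99 with the cluster term). The immediate early transcription factor gene Egr1 went from 713 ± 84.2 to 244 ± 127, with a difference of -1.64 ± 0.32 (adjusted p = 0.0221; -1.21 with the term). Itgae, the integrin chain that binds E-cadherin on epithelia, changed by -0.52 ± 0.11 (adjusted p = 0.0346; -0.59 with the term). The Egr1 call ended without any 1 unirradiated array, the Il7r call without any 1 unirradiated array or day-5 array 1, 2, 3, 5 or 6, and the Itgae call without day-5 array 1, 5 or 6 or unirradiated array 2, 3 or 4.

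The effector list moved up at day 5, with 4 of 21 members risen and none fallen, over all probe sets and over the list alone (camera, adjusted p = 0.0106, or 0.443 with an estimated correlation). The members included the galectin gene Lgals1 at 2.12 ± 0.48 (adjusted p = 0.0413; 1.53 with the cluster term) and the annexin gene Anxa2 at 1.00 ± 0.22 (adjusted p = 0.0406; 0.89 with the term). The granzyme gene Gzmb stayed outside the threshold at 0.72 ± 0.38 (adjusted p = 0.405), as did the chemokine gene Ccl5 at 0.23 ± 0.37 (adjusted p = 0.787). The naive and quiescence list moved down, with 1 of 28 members fallen, or 3 over the list alone (adjusted p = 0.0111, or 0.38 with an estimated correlation). Oxidative phosphorylation moved up with 39 of 53 members higher and none called, or 1 over the list alone (adjusted p = 0.00432, or 0.443 with an estimated correlation), and so did the proteasome list with 26 of 33 higher and none called (adjusted p = 0.00108, or 0.443 with an estimated correlation). In glycolysis, 1 of 16 members rose, the lactate dehydrogenase gene Ldha at 0.66 ± 0.12 (adjusted p = 0.00992; 0.69 with the term), and the list stayed outside the threshold (adjusted p = 0.136). These lists passed with the cluster term too, with adjusted p = 0.00937 for effector molecules, 0.000575 for naive genes, 1.04e-06 for oxidative phosphorylation and 2.97e-09 for the proteasome. All 4 lists were lost with fry and also with a block for replicate number. The effector list was lost with no filter too, and the naive list with a filter at the 50th percentile. The naive list was lost without day-5 array 4 or unirradiated array 3, and oxidative phosphorylation without unirradiated array 3. Ldha was lost without unirradiated array 1 or 4, Lgals1 without any 1 unirradiated array or day-5 array 1, 2, 3, 5, 6 or 7, and Anxa2 without any 1 unirradiated array or day-5 array 1, 3, 4, 5 or 6.

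The other lists did not pass at day 5. Memory markers had adjusted p = 0.475, NK-type receptors 0.503, immediate activation genes 0.503, interferon-stimulated genes 0.392, cholesterol and fatty acid synthesis 0.634, ribosomal proteins 0.835, apoptosis regulators 0.469, p53 targets 0.222, cytokine receptors and signalling 0.392, and chemokine receptors and adhesion 0.392. Among marker lists, CD8 identity had adjusted p = 0.53, B cells 0.316, plasma cells 0.924, myeloid cells 0.392, neutrophil lineage 0.578, erythroid cells 0.228, CD4 T cells 0.776, dendritic cells 0.634, and stroma and vessels 0.529. NK cells and megakaryocytes had too few tested genes for a test, and none of those genes was called by limma in any comparison.

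In all, limma called 69 of 8695 probe sets at day 5, 36 up and 33 down, of which 14 rose and 9 fell at least 2-fold, and 138 with the cluster term, 65 of them the same. Within cluster 2, 5 day-5 arrays against 4 unirradiated hosts gave 206. The count was 23, 23, 25 and 13 without unirradiated arrays 1 to 4, and 35, 42 and 45 without day-5 arrays 1, 3 and 6.

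**Figure D2:**
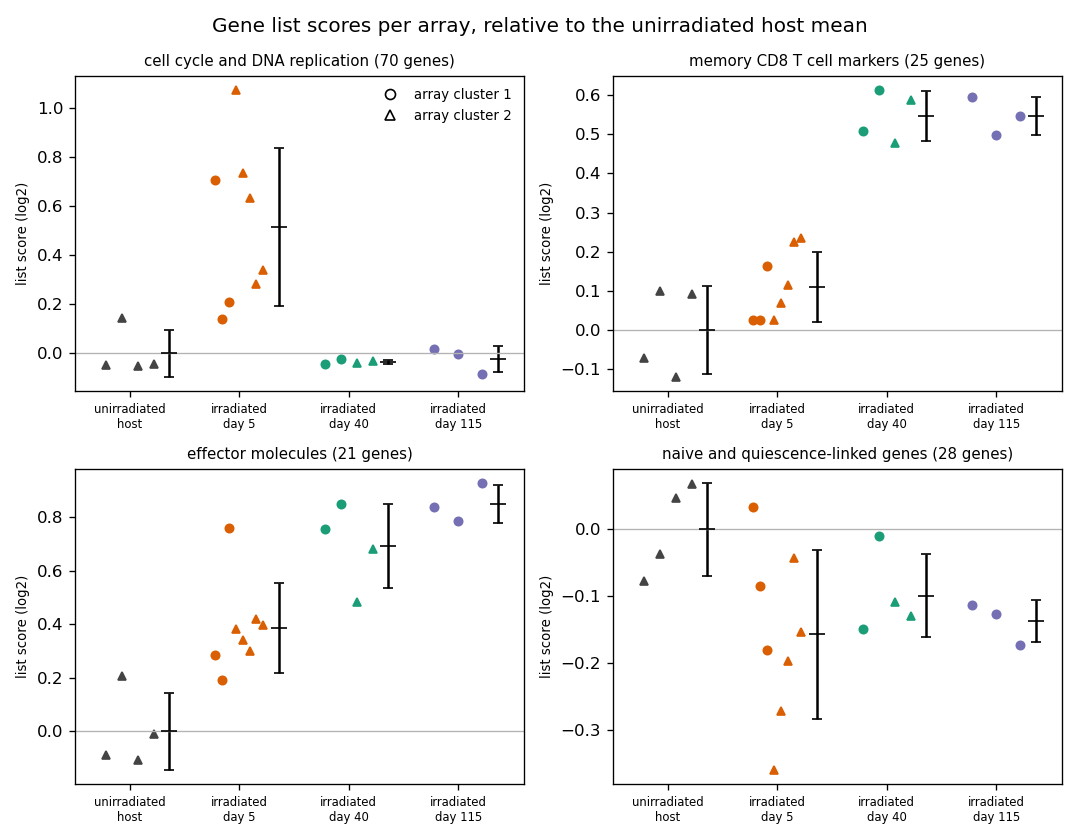
List scores per array (log2, relative to the mean of unirradiated hosts) for the cell cycle, memory, effector and naive lists in each group. Points are arrays (circles cluster 1, triangles cluster 2) and bars give mean ± SD, and the cell cycle score of day-5 arrays ran from 0.141 to 1.07.

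Day 40 against unirradiated hosts asked how cells at the later time differed from the reference sorted at day 6. The chemokine gene Ccl5, stored as transcript by memory CD8 T cells, rose from 316 ± 179 (n = 4) to 2160 ± 484 (n = 4), a log2 difference of 2.84 ± 0.43 (adjusted p = 0.00122; 2.99 with the cluster term). S100a6 stood at 526 ± 83.5, a rise of 2.92 ± 0.31 (adjusted p = 2.31e-05; 3.08 with the term), and Cxcr3 at 1030 ± 152, a rise of 2.56 ± 0.24 (adjusted p = 4.57e-06; 2.45 with the term). Fasl, the ligand by which T cells kill through Fas, rose from 28.7 ± 2.69 to 112 ± 19.4, by 1.51 ± 0.10 (adjusted p = 9.25e-08; 1.44 with the term). The perforin gene Prf1 rose by 0.79 ± 0.15 (adjusted p = 0.00834; 0.72 with the term). Gzmm, a granzyme of cytotoxic cells, rose by 1.77 ± 0.35 (adjusted p = 0.0125; 1.34 with the term).

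Both chains of the IL-18 receptor rose at day 40. Il18r1, a chain of the IL-18 receptor, went from 140 ± 34.8 to 421 ± 89.2, a rise past the threshold (adjusted p = 0.000543; log2 difference of 1.70 with the cluster term), and Il18rap, its partner, rose by 1.04 ± 0.16 (adjusted p = 0.00185; 0.87 with the term). Stat4, a signal transducer of IL-12, rose by 1.46 ± 0.26 (adjusted p = 0.00591; 1.20 with the term), and the chemokine receptor gene Ccr2 by 1.35 ± 0.20 (adjusted p = 0.000809; 1.41 with the term). Among the falls, Cnn3 changed by -1.95 ± 0.15 (adjusted p = 5.49e-07; -1.90 with the term), Egr1 by -2.19 ± 0.37 (adjusted p = 0.00339; -1.61 with the term), and Itgae by -1.05 ± 0.13 (adjusted p = 0.000109; -1.14 with the term). The Itgae difference was -0.58 with a pseudocount of 64 and -1.42 with a pseudocount of 1. Il7r stood at 2240 ± 697 and was outside the threshold (0.30 ± 0.29, adjusted p = 0.628). Top2a, at 35.2 ± 2.43, was too (-0.07, adjusted p = 0.948).

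Memory markers moved up as a list at day 40. Of 25 members, 6 rose, 1 fell and 18 did neither, and 10 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 3.85e-06, or 0.00741 with an estimated correlation). The effector list had 7 of 21 members risen, or 9 risen and 1 fallen over the list alone (adjusted p = 1.04e-05, or 0.103 with an estimated correlation). Cytokine receptors and signalling had 5 of 26 risen, or 9 over the list alone (adjusted p = 3.22e-05, or 0.0412 with an estimated correlation). Memory, effector and cytokine lists all passed within cluster 2, with adjusted p = 2.49e-05, 5.23e-05 and 2.22e-06. These passes are not separate results, since the memory list shares Il18r1 and Il18rap with the cytokine list and Ccl5 and Fasl with the effector list. The B-cell marker list moved up with 12 of 15 members higher, none called by limma over all probe sets and 3 over the list alone (adjusted p = 0.0122, or 0.736 with an estimated correlation), and was lost with fry and without day-40 array 2. Within cluster 2 it moved up too (camera, adjusted p = 0.000212). The cell cycle list stayed outside the threshold (adjusted p = 0.62). Oxidative phosphorylation was outside it as well (camera, adjusted p = 0.0897), but moved down within cluster 2 (adjusted p = 0.000264).

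At day 40, 129 probe sets were called, 100 up and 29 down, and 46 of these rose and 16 fell at least 2-fold. With the cluster term the count was 193, of which 111 were the same, and within cluster 2 alone it was 265. It was 62, 70, 54 and 58 without unirradiated arrays 1 to 4, and 66, 82 and 82 without day-40 arrays 1, 2 and 4.

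**Figure D3:**
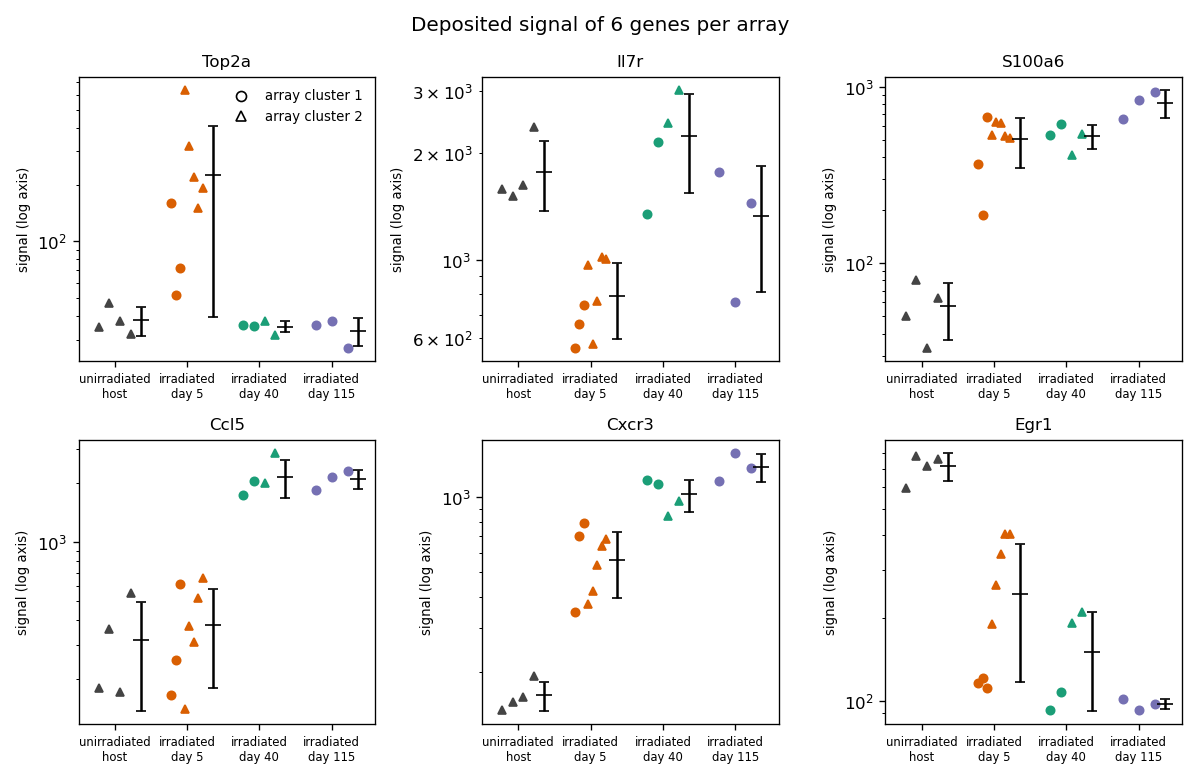
Deposited signal (log axis) of Top2a, Il7r, S100a6, Ccl5, Cxcr3 and Egr1 per array in each group, with mean ± SD beside the points. The mean of Ccl5 was 316 in unirradiated hosts, 378 at day 5, 2160 at day 40 and 2110 at day 115.

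Day 115 against unirradiated hosts asked which differences from the reference sorted at day 6 were present at the last time. S100a6 reached 815 ± 146 (n = 3), a rise of 3.54 ± 0.33 (adjusted p = 2.36e-06; 3.85 with the cluster term), and Cxcr3 reached 1320 ± 174, a rise of 2.93 ± 0.25 (adjusted p = 1.37e-06; 2.70 with the term). Ccl5 stood at 2110 ± 230, up by 2.83 ± 0.47 (adjusted p = 0.000907; 3.11 with the term). Gzmm rose by 2.70 ± 0.38 (adjusted p = 0.000205; 1.84 with the term) and Ccr2 by 1.34 (1.45 with the term). Tnfrsf1b, a receptor for TNF found on memory T cells, rose by 1.45 ± 0.15 (adjusted p = 8.92e-06; 1.35 with the term). Egr1 fell to 97.4 ± 4.27, a difference of -2.68 ± 0.40 (adjusted p = 0.00046; -1.51 with the term, adjusted p = 0.00169), and Itgae to 22.8 ± 3.11 (adjusted p = 4.36e-05), under the filter level.

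The immunoglobulin light chain gene Igkv6-23 rose from 40.8 ± 8.39 to 630 ± 445, by 3.31 ± 0.40 (adjusted p = 4.66e-05; 3.16 with the cluster term). Txndc5, a protein disulfide isomerase of the endoplasmic reticulum, rose from 112 ± 24 to 860 ± 166, by 2.78 ± 0.40 (adjusted p = 0.000263; 1.69 with the term). The liver gene Alb rose from 26 ± 1.52 to 342 ± 285, by 2.43 ± 0.51 (adjusted p = 0.00364; 2.30 with the term, adjusted p = 0.0453). The immunoglobulin heavy chain gene Ighm rose by 1.92 ± 0.33 in its brightest probe set (adjusted p = 0.0013; 0.95 with the term), while its other probe sets differed by -0.017 to 0.85, and the MHC class II gene H2-Aa by 1.98 (1.07 with the term, adjusted p = 0.213).

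Several large falls at day 115 shrank with the cluster term. The stress-response gene Ddit4 changed by -3.65 ± 0.84 on groups alone (adjusted p = 0.00582) and by -1.07 with the term (adjusted p = 0.119). The chromatin remodelling gene Smarca2 changed by -3.55, or -0.72 with the term (adjusted p = 0.289), and the topoisomerase gene Top2b by -3.16, or -1.26 with the term (adjusted p = 0.089). Nras went from -2.85 ± 0.93 (adjusted p = 0.0306) to 0.15 with the term (adjusted p = 0.795). The IL-2 receptor chain gene Il2rb was up by 0.52 ± 0.17 (adjusted p = 0.0279) and by 0.22 with the term (adjusted p = 0.471). The Nras call also ended without any 1 day-115 array or unirradiated array 1, 3 or 4, and that of Il2rb without day-115 array 1 or 3 or unirradiated array 1, 2 or 3.

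In the lists at day 115, 12 of 25 memory markers rose and 2 fell, or 12 and 3 over the list alone (camera, adjusted p = 0.00303, or 0.179 with an estimated correlation), and with the cluster term 9 rose and 2 fell (adjusted p = 2.87e-05, or 0.0335 with an estimated correlation). Effector molecules had 9 of 21 risen and 1 fallen, or 11 and 1 over the list alone (adjusted p = 0.00303, or 0.353 with an estimated correlation), and with the term 8 rose (adjusted p = 0.00069). Cytokine receptors had 13 of 26 risen, in both adjustments (adjusted p = 0.00303, or 0.229 with an estimated correlation), and 4 with the term (adjusted p = 0.00069). Of 15 B-cell markers, 7 rose, or 10 over the list alone (adjusted p = 0.00303, or 0.633 with an estimated correlation), and 2 with the term (adjusted p = 0.00397, or 0.454 with an estimated correlation). Immediate activation genes did not move on groups alone, with 4 of 29 risen and 4 fallen (adjusted p = 0.915), and moved down with the cluster term, with 4 fallen (adjusted p = 0.00769, or 0.454 with an estimated correlation). Their scores at day 115, from -0.0387 to 0.00186, lay within the range of unirradiated hosts, -0.0448 to 0.11, so the move rested on the cluster step, with scores of 0.312 to 0.601 in day-5 arrays 1 to 3 and -0.157 to 0.0111 in the other day-5 arrays. Glycolysis was outside the threshold on groups alone, with 6 of 16 risen (adjusted p = 0.104), and passed with the term, with 2 risen (adjusted p = 0.00864, or 0.454 with an estimated correlation). Glycolysis also passed with quantile normalisation, without day-115 array 3 and without unirradiated array 2. The pyruvate kinase gene Pkm rose by 1.89 ± 0.31 (adjusted p = 0.000924; 1.20 with the term, adjusted p = 0.022).

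The call count at day 115 was 2424, with 1309 up and 1115 down, of which 382 rose and 510 fell at least 2-fold. With the cluster term it was 384, with 274 up and 110 down, and 274 of those were also called on groups alone. No cluster held both groups, so no value within a cluster could be given. It was 1554 without day-115 array 2 and 1610 without day-115 array 3.

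**Figure D4:**
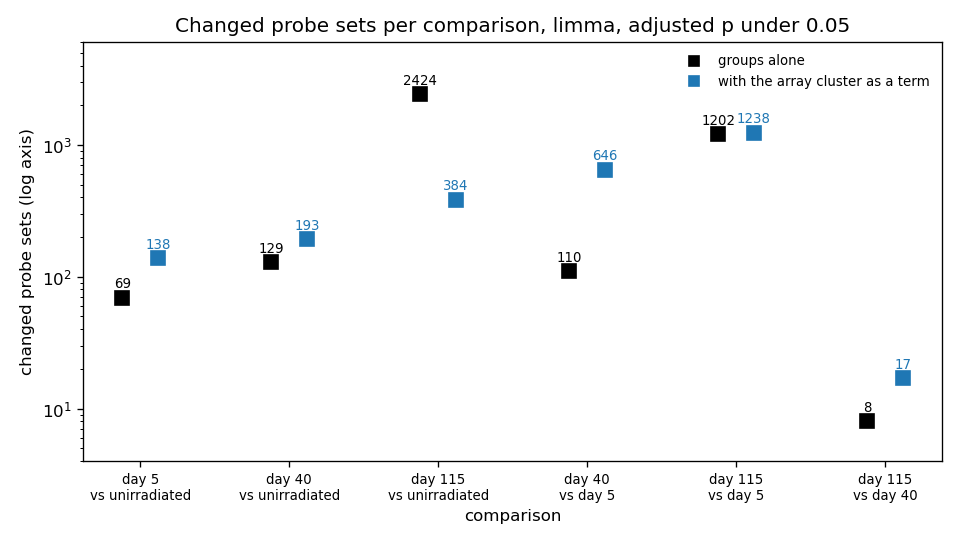
Probe sets past an adjusted p of 0.05 in each of the 6 comparisons (log axis), with black squares for the fit on groups alone and blue squares for the fit with the array cluster as a term. Day 115 against unirradiated hosts went from 2424 to 384, and day 40 against day 5 from 110 to 646.

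The 3 comparisons share their reference. Day 5 and day 40 shared 26 calls, 8 up and 18 down, day 5 and day 115 shared 46, 21 up and 25 down, and day 40 and day 115 shared 123, 95 up and 28 down. S100a6, Cxcr3, Cnn3, Egr1 and Nrip1 were in all 3. Lists of these lengths, if independent, would share 0.414 calls up and 0.11 down for days 5 and 40. For days 5 and 115 it would be 5.42 and 4.23, and for days 40 and 115 it would be 15.1 and 3.72. These values take no account of the shared reference. Simulated unchanged data with the same shared reference gave a median of 0 shared calls between day 5 and day 40 over 20 draws. Unchanged groups yield few calls to share, so a count of 0 in such data is no measure of chance overlap. In the same draws, the median correlation of the differences was 0.579, against 0.73 observed. With the real cluster step added to the simulation, the median was again 0 shared calls. However, the median correlations were then 0.883, 0.885 and 0.898 for the 3 pairs, against 0.73, 0.771 and 0.898 observed. When the unirradiated arrays were split between the comparisons, the medians over 6 splits were 4.5, 7 and 32.5 shared calls, in the same order. With the cluster term the counts were 42, 47 and 142. Without unirradiated arrays 1 to 4 in turn, the shared calls were 14, 9, 13 and 10 for days 5 and 40, 18, 14, 17 and 11 for days 5 and 115, and 61, 66, 54 and 54 for days 40 and 115. For days 5 and 115 they were 25, 24, 25 and 30 without day-5 arrays 1, 2, 3 and 6 and 30 without day-115 array 1, and for days 40 and 115 they were 60 and 78 without day-40 arrays 1 and 2.

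Day 40 against day 5 asked what changed between the early and the later time. Ccl5 rose by 2.62 ± 0.37 (adjusted p = 0.00115; 2.61 within cluster 1 and 2.69 within cluster 2), and Fasl by 1.53 ± 0.09 (adjusted p = 6.04e-09; 1.57 and 1.46). Il7r rose from 787 ± 189 (n = 8) to 2240 ± 697 (n = 4), by 1.47 ± 0.25 (adjusted p = 0.0054; 1.37 and 1.66). Il18r1 rose by 1.25 ± 0.18 (adjusted p = 0.0012; 1.27 and 1.34) and Prf1 by 0.86 ± 0.13 (adjusted p = 0.00158; 0.68 and 0.98). Itgb1, the beta chain of integrins that mark memory T cells, rose by 1.63 ± 0.30 (adjusted p = 0.0102; 2.03 and 1.51), and Txnip, an inhibitor of glucose uptake, by 1.48 ± 0.24 in its brighter probe set (adjusted p = 0.00284; 1.30 and 1.74), but not in another (-0.14, adjusted p = 0.668). The Itgb1 call ended without day-40 array 4.

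Genes of division fell between these times. Pclaf, a partner of the replication clamp, went from 251 ± 182 to 25.1 ± 5.83, a difference of -2.36 ± 0.44 (adjusted p = 0.0102; -1.44 within cluster 1 and -2.87 within cluster 2). Top2a changed by -1.91 ± 0.39 (adjusted p = 0.0194; -0.98 and -2.48), Mki67 by -1.79 ± 0.38 (adjusted p = 0.0218; -1.14 and -2.18), and Cdk1 by -1.53 ± 0.28 (adjusted p = 0.0102; -1.19 and -1.79). The other probe set of Mki67 stayed outside the threshold (-0.22, adjusted p = 0.189). With pseudocounts of 64 and 1, the difference of Pclaf was -1.60 and -2.88, and that of Mki67 was -1.05, outside the threshold, and -2.45. Isg15, an interferon-induced modifier, changed by -0.76 ± 0.15 (adjusted p = 0.013). Without day-40 array 4 the calls of Pclaf, Top2a, Cdk1, Mki67 and Isg15 ended, without day-40 array 3 those of Top2a and Mki67, and without day-40 array 1 or 2 that of Mki67.

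Of 70 cell cycle genes, 6 fell and none rose over all probe sets, and 37 fell when adjusted over the list alone (camera, adjusted p = 2.65e-27, or 0.0333 with an estimated correlation). With the cluster term, 27 fell and 1 rose. Oxidative phosphorylation moved down with 3 of 53 members higher and none called by limma in either adjustment (camera, adjusted p = 6.35e-10, or 0.0333 with an estimated correlation), and with the term 7 fell and 1 rose, among them the cytochrome oxidase gene Cox7b at -0.86. Proteasome subunits moved down with 5 of 33 higher and none called, or 4 over the list alone (adjusted p = 5.6e-06, or 0.21 with an estimated correlation), and were lost with fry. Memory markers moved up, with 9 of 25 risen, or 11 risen and 1 fallen over the list alone (adjusted p = 2.9e-07, or 0.00463 with an estimated correlation), and within each cluster (adjusted p = 1.65e-06 and 0.0051). Cytokine receptors had 4 of 26 risen, or 8 over the list alone (adjusted p = 6.11e-06, or 0.0287 with an estimated correlation). Effector molecules had 6 of 21 risen and 1 fallen, or 7 and 1 over the list alone (camera, adjusted p = 0.0307, or 0.513 with an estimated correlation). They passed within cluster 1 (adjusted p = 0.0221) but not within cluster 2 (adjusted p = 0.398). They were lost with the term, with a filter at the 50th percentile and with a block for replicate number. Removal of day-5 array 1 or 2 or day-40 array 2 ended the call too. B-cell markers were outside the threshold (camera, adjusted p = 0.0637). They moved up within cluster 2 (adjusted p = 0.00418) but did not pass within cluster 1 (adjusted p = 0.694).

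Between these times 110 probe sets were called, 83 up and 27 down, and 646 with the cluster term, which included all 110. Within cluster 1, with 3 and 2 arrays, limma called 1, with 670 at an unadjusted p under 0.05, and within cluster 2, with 5 and 2 arrays, 486. The count was 187, 72 and 73 without day-5 arrays 4, 5 and 8, and 67 and 25 without day-40 arrays 3 and 4.

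Day 115 against day 5 asked the same of the last time. Ccl5 rose by 2.60 ± 0.41 (adjusted p = 0.000827; 2.76 within cluster 1), Fasl by 1.34 ± 0.10 (adjusted p = 1.73e-07; 1.28) and Cxcr3 by 1.27 ± 0.23 (adjusted p = 0.00196; 1.17). Tnfrsf1b rose by 1.37 ± 0.13 (adjusted p = 5.61e-06; 1.33) and Prf1 by 0.70 ± 0.14 (adjusted p = 0.00438; 0.55). Igkv6-23 rose by 2.83 ± 0.35 (adjusted p = 0.000105; 2.79) and Txndc5 by 2.48 ± 0.35 (adjusted p = 0.000322; 1.93). Ifitm10, of the interferon-induced transmembrane family, rose by 2.04 ± 0.26 (adjusted p = 0.00012; 1.63). Il7r stayed outside the threshold at 0.69 ± 0.27 (adjusted p = 0.0927) and passed with the cluster term at 0.99 (adjusted p = 0.0199).

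Division genes were lower at day 115 than at day 5. Pclaf changed by -2.50 ± 0.49 (adjusted p = 0.00346; -1.46 within cluster 1, and -1.66 or -3.10 with a pseudocount of 64 or 1), the replication clamp gene Pcna by -1.87 ± 0.33 (adjusted p = 0.00182; -1.33), Top2a by -1.97 ± 0.44 (adjusted p = 0.00731; -1.04) and the cyclin gene Ccna2 by -0.96 (adjusted p = 0.00387; -0.95). The proteasome gene Psmc6 changed by -2.14 ± 0.48 (adjusted p = 0.00804; -1.14), and the interferon-induced GTPase gene Ifi47 by -1.24 (adjusted p = 0.00152; -0.95 with the cluster term).

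Of 70 cell cycle genes, 24 fell and 1 rose, or 36 and 4 over the list alone (camera, adjusted p = 5.48e-09, or 0.522 with an estimated correlation), and the list passed within cluster 1 (adjusted p = 2.41e-07). Memory markers had 11 of 25 risen and 1 fallen, or 14 and 3 over the list alone (adjusted p = 0.000573, or 0.0829 with an estimated correlation). Cytokine receptors had 8 of 26 risen, or 9 over the list alone (adjusted p = 0.000538, or 0.0933 with an estimated correlation). B-cell markers had 6 of 15 risen, or 7 over the list alone (adjusted p = 0.000573, or 0.522 with an estimated correlation). Oxidative phosphorylation had 7 of 53 fallen, or 12 over the list alone (adjusted p = 0.00316, or 0.522 with an estimated correlation). Proteasome subunits had 5 of 33 fallen (adjusted p = 0.028, or 0.724 with an estimated correlation), and effector molecules 7 of 21 risen (adjusted p = 0.0317, or 0.545 with an estimated correlation). The proteasome list was lost with fry, with a block for replicate number, and without day-5 array 1 or 6 or day-115 array 1 or 3. The effector list was lost with a filter at the 50th percentile and without day-5 array 1 or 2 or day-115 array 1 or 3.

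The comparison held 1202 calls, 715 up and 487 down, and 1238 with the cluster term, 665 of them the same. Within cluster 1, with 3 arrays per group, 112 were called, and without day-115 array 2 the pooled count was 590.

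Day 115 against day 40 asked whether the late state still moved. The potassium channel gene Kcnj8 rose by 0.73 ± 0.10 (adjusted p = 0.0038; 0.63 with the cluster term) and the immunoglobulin gene Igkv4-70 by 0.71 ± 0.12 (adjusted p = 0.0206; 0.71 with the term). The liver genes Mup5 and Serpina1c rose by 1.39 ± 0.25 (adjusted p = 0.0264; 1.34 with the term) and 1.11 ± 0.20 (adjusted p = 0.0264; 1.00 with the term). Ccl5 (-0.01 ± 0.47, adjusted p = 0.992), Cxcr3 (0.36 ± 0.25, adjusted p = 0.505) and Il7r (-0.77 ± 0.31, adjusted p = 0.313) stayed outside the threshold. The Igkv4-70 call ended without day-40 array 4, that of Mup5 without day-40 array 2, 3 or 4 or day-115 array 2, and that of Serpina1c without those or day-115 array 3. Only the B-cell list passed, with 12 of 15 members higher, none called by limma over all probe sets and 3 over the list alone (adjusted p = 0.0188, or 0.997 with an estimated correlation), and it was lost with fry, a pseudocount of 1, no filter or a filter at the 50th percentile, and without day-40 array 1 or day-115 array 1.

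In this last comparison, 8 probe sets were called, all up, and 17 with the cluster term, 11 up and 6 down. Quantile normalisation gave 10 up and 2 down, and centring on the median 17 up and 3 down. Within cluster 1, with 3 and 2 arrays, limma called 0, with 295 at an unadjusted p under 0.05. The count was 85, 5, 5 and 3 without day-40 arrays 1 to 4, and 40 and 18 without day-115 arrays 1 and 3.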

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

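Dixon's test was run 258 times on signals and list scores within a group, which chance alone would pass in about 1 in 20 groups, and 21 values lay far from the others of their group where 12.9 would by chance. The 21 values came from 6 arrays. Differences between times were looked for among named genes whose effects against unirradiated hosts at day 5 and at a later time had opposite signs. Which tests of explanations were chosen after a result was seen is said at each of them.

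Among day-5 samples, array 3 stood apart in 4 values. Its Fasl signal was 39.3, where the other 7 lay between 23 and 28.9, and its signal of Ctla2b, a protease inhibitor of cytotoxic cells, was 84.9 against 29.9 to 45.7. Its effector list score was 0.76 against 0.194 to 0.419, and its score of NK-type receptors 0.341 against 0.00101 to 0.131. Day-5 array 2 had a plasma-cell score of 0.304, where the others lay between -0.0743 and 0.0639.

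At day 40, array 1 had a Ccnb2 signal of 129 against 85.7 to 87.6, an Alb signal of 30.8 against 22.4 to 23.4, and an apoptosis list score of -0.023 against 0.159 to 0.171. Array 2 had a cholesterol score of -0.168 against -0.0686 to -0.0629 and a B-cell score of 0.759 against 0.243 to 0.33. Array 3 had a Pclaf signal of 33.8 against 21.5 to 23.1 and a Kcnj8 signal of 32.1 against 44.6 to 46.7.

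Unirradiated array 2 lay above the other 3 in 9 values. Its signals were 332 for Lgals1 against 122 to 138, 60.7 for Ctla2b against 18.5 to 20.8, 70.4 for Pclaf against 39.2 to 41, and 32.8 for Mki67 against 15.6 to 17.6. Its scores were 0.144 for the cell cycle against -0.0528 to -0.0428, 0.11 for immediate activation genes against -0.0448 to -0.0299, 0.214 for interferon-stimulated genes against -0.0801 to -0.0617, 0.0707 for cholesterol synthesis against -0.0315 to -0.0179, and 0.142 for plasma cells against -0.0578 to -0.0321. Without this array, day 5 against unirradiated hosts gave 23 calls, and without unirradiated array 1, 3 or 4 it gave 23, 25 or 13.

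For 13 gene and time pairs the effects had opposite signs, at least 1 of them passed the threshold, and the difference itself, tested by limma between the 2 times, passed with and without the cluster term. In many of these pairs the effect at 1 time was close to 0. Genes with effects of the same sign at both times, such as Ccl5, were not looked for here. Between day 5 and day 40, the effect of Top2a differed by -1.91 (1.84 and then -0.07), that of Cdk1 by -1.53 (1.41 and -0.11) and that of Stmn1 by -2.30 (1.94 and -0.36). The effect of Il7r differed by 1.47 (-1.17 and 0.30), that of Fasl by 1.53 (-0.02 and 1.51) and that of Prf1 by 0.858 (-0.07 and 0.79). Between day 5 and day 115, Top2a differed by -1.97 (1.84 and -0.12) and Ccnb2 by -1.15 (1.03 and -0.12). In the same pair of times, Prf1 differed by 0.697 (-0.07 and 0.63), the receptor gene Klrk1 by 0.456 (-0.01 and 0.44), Fasl by 1.34 (-0.02 and 1.32), Alb by 2.43, which is the whole of its effect at day 115, and Mup5 by 1.37 (-0.02 and 1.35).

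The rise of liver genes at day 115 came from 2 arrays. The tests of its explanations were chosen after the values were seen, from a list of liver genes written before the test. Alb was at 408 and 587 in day-115 arrays 2 and 3, where the highest of the other 17 arrays was 32. If RNA of liver cells had entered these samples, other abundant liver genes should stand out as well, and 12 of 24 further liver genes were above all other 17 arrays in both, where chance gives 0.585%, Mup3 at 155 and 146 against 40.1 at most and Serpina1b at 163 and 93.2 against 46.1. That goes with RNA of liver cells in these samples, although a sort for T cells should have removed such cells. Ttr, another abundant liver transcript, stayed at 26.7 and 23.1 against 25.1 at most. Other liver genes were not raised either, such as Fabp1, at 20.4 and 19.7 against 24.7, and Apob, at 11.6 and 13.6 against 15.3. Apoh, 1 of the 12, lay under the filter level at 22 and 20.2. The array cluster may be set aside as the cause, since the highest Alb signal of the other 6 arrays of cluster 1 was 32, and a biological difference was not tested.

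The immunoglobulin signal at day 115 was weighed in the same way, with tests chosen after the values were seen, and Igkv6-23 was at 1140, 370 and 376 in the 3 day-115 arrays and from 32.3 to 312 in the other 5 of cluster 1. Within cluster 1 it was higher than at day 5 by 2.79 ± 0.51 (limma, adjusted p = 0.0318), which counts against the array cluster as the cause of that rise, but 5 of 22 immunoglobulin genes were above all other cluster-1 arrays and Ighm differed by 0.43 (adjusted p = 0.26), so the cluster stays open for the others. If B cells had been among the sorted cells, their other markers should be raised, and 2 of 14, Vpreb3 and Jchain, were above all other cluster-1 arrays, where chance gives 1.79%, while H2-Aa, at 786, and Cd74, at 470, peaked in day-115 array 1 with Igkv6-23, the other 2 day-115 arrays lay under the 400 and 239 of day-40 array 2 there, and Cd79a differed by -0.15 ± 0.16 and Cd79b by -0.11 ± 0.30. The B-cell list, which includes Ighm, moved up within cluster 1 (camera, adjusted p = 0.0184), and with the cluster term was at 0.00636, or 0.522 with an estimated correlation. If plasma cells had been, 1 of 6 markers was raised, Jchain again, at 1.04 ± 0.27 (limma, adjusted p = 0.0885), while Xbp1 was at -0.32 and Sdc1 at -0.22, and on these tests B cells and plasma cells among the sorted cells cannot be told apart from their absence, and other biological sources were not tested.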

How the results depend on the processing

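Of the values of named genes and lists under the alternatives chosen beforehand, 8467 results stayed the same, 727 were weaker, 68 stronger and 0 reversed. Under alternatives chosen after seeing the data, 1158 were the same, 224 weaker, 36 stronger and 6 reversed. A result that passed the threshold in neither fit counted as the same, whatever its sign. Only a result that passed in at least 1 of the 2 fits could count as reversed. The numbers of same results therefore include many that never passed. Of the counts, 203 stayed within 1.5-fold under the alternatives chosen beforehand and 84 moved. Under those chosen after seeing the data, 23 stayed and 20 moved. Named top genes kept their calls in 82 of 85 cases with quantile normalisation, 83 with centring on the median, 78 with a pseudocount of 64, 66 with only the groups compared, 74 with the array cluster block and 69 with the donor sex block, and in 6 of 25 cases within array cluster 1 and 49 of 50 within array cluster 2. For every count that moved, below, the cause was not tested.

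Day 5 against unirradiated hosts gave 69 calls as the main count. It gave 40 with only the groups compared, 450 with arrayWeights, 907 with only day-5 arrays 1 to 4, 44 with day-5 arrays 1 and 2 left out, 138 with the array cluster block and 206 within array cluster 2. Leaving out single arrays gave 13 (unirradiated host replicate 4) to 79 (day-5 replicate 7). Day 40 against unirradiated hosts, at 129, gave 271 with only the groups compared, 963 with arrayWeights, 265 within array cluster 2 and 80 with the donor sex block, and 54 (unirradiated host replicate 3) to 139 (day-40 replicate 3) without single arrays. Day 115 against unirradiated hosts, at 2424, gave 4094 with arrayWeights, 384 with the array cluster block, 1542 with the donor sex block, 201 with day-115 arrays 2 and 3 left out, and 1554 (day-115 replicate 2) to 1998 (unirradiated host replicate 2) without single arrays.

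Day 40 against day 5, at 110, gave 46 with only the groups compared, 1484 with arrayWeights, 29 with only day-5 arrays 1 to 4, 880 with only day-5 arrays 5 to 8, 189 with day-5 arrays 1 and 2 left out, 646 with the array cluster block, 1 within array cluster 1 and 486 within array cluster 2. Without single arrays it ranged from 25 (day-40 replicate 4) to 187 (day-5 replicate 4). Day 115 against day 5, at 1202, gave 1865 with no filter, 659 with only the groups compared, 3708 with arrayWeights, 214 with only day-5 arrays 1 to 4, 3082 with only day-5 arrays 5 to 8, 2326 with day-5 arrays 1 and 2 left out and 112 within array cluster 1. Single arrays left out gave 590 (day-115 replicate 2) to 1647 (day-5 replicate 3).

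Day 115 against day 40, at 8, gave 20 with arrays centred on the median, 63 with no filter, 3 with a filter at the 50th percentile, 3023 with arrayWeights, 5 with 1 probe set per gene, 17 with the array cluster block and 19 with day-115 arrays 2 and 3 left out. It gave 0 by limma with only the groups compared and 0 within array cluster 1, where 295 were at an unadjusted p under 0.05. Single arrays left out gave 3 (day-40 replicate 4) to 85 (day-40 replicate 1).

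Of 96 pathway tests, 23 passed and 6 did so with an estimated correlation. Of 54 marker tests, 4 passed, 0 with an estimated correlation and 2 with fry. The count was 7 with the values within array cluster 1. Comparisons against unirradiated hosts could not be run there and kept their main calls in that count. Shared calls of days 5 and 40, at 26, were 16 with a filter at the 50th percentile, 4.5 with split unirradiated hosts, 42 with the array cluster block, and 9 (unirradiated host replicate 2) to 29 without single arrays. Those of days 5 and 115, at 46, were 7 with split hosts, 15 with day-115 arrays 2 and 3 left out, and 11 (unirradiated host replicate 4) to 51 without single arrays. Those of days 40 and 115, at 123, were 32.5 with split hosts, 77 with the donor sex block, 62 with day-115 arrays 2 and 3 left out, and 54 (unirradiated host replicate 3) to 135 without single arrays.

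With the array cluster block, 103 of the 2424 calls of day 115 against unirradiated hosts turned direction, and so did 6 results named in the text or tested as a list. The cause was not tested. Nras was at 0.15, Pim1 at -0.037, Gbp3 at 0.033, Cycs at 0.13 and Psme3 at 0.058. The neutrophil lineage list, up but outside the threshold on groups alone (camera, adjusted p = 0.915), moved down with the block (adjusted p = 0.0392). Its scores at day 115, from 0.036 to 0.0774, were not under those of unirradiated hosts, -0.101 to 0.0687. That move therefore rested on the cluster step, with scores of 0.364 and 0.489 in day-5 arrays 2 and 3.

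No label says that replicate numbers pair the samples, and the correlations did not settle it. Across 21 pairs of the same number the correlation after removal of group means ran from -0.667 to 0.764. The median was 0.0679, against -0.0127 in 107 other pairs, and only 8 were over 0.1. Those values also reflect the array clusters. With the cluster step removed too, the pair of day-5 and day-40 arrays 3 went from -0.667 to 0.542. The pair of day-5 and day-40 arrays 2 went from 0.624 to -0.36. The fit with a replicate block kept only the 2 groups compared and the replicate numbers they share, 8 or 6 arrays. It gave 1242 calls for day 5, 235 for day 40 and 2634 for day 115 against unirradiated hosts. Between times it gave 0 for day 40 against day 5 by limma, 198 for day 115 against day 5 and 0 for day 115 against day 40. It gave 7 marker lists. These counts are not the effect of the block alone, since day-5 arrays 1 to 4 without a block gave 907 against unirradiated hosts. With that block 65 of 85 named top genes kept their calls.

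Signal over background limits which genes were measured. Probe sets under a mean of 26.1 were not tested, and Cd44, Il2ra, Ifng and Klrg1 were among those.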

Other observations

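In this part, the fits with the cluster term and the gene and list tests within a cluster were chosen after the arrays had been seen. The tests of signs and the random splits were written before their results were seen, and a further test chosen after is marked. Some immediate early genes were lower at day 115 than at day 5 where the array cluster was held fixed. Fos, the partner of Jun in the AP-1 factor, changed by -2.88 between these times with the cluster term and by -3.52 within cluster 1. This rested on day-5 arrays 1 to 3, with Fos signals of 273.6, 907 and 146.4, since day-5 arrays 4 to 8 lay from 14.8 to 28.3 and the day-115 arrays from 13.8 to 16.6. The phosphatase gene Dusp1 changed by -1.53 with the term and -1.84 within cluster 1, and the heat shock gene Hspa1b by -1.53 and -1.82. Of 29 immediate activation genes, 7 fell and 1 rose with the term (camera, adjusted p = 0.00636, or 0.522 with an estimated correlation), and the list moved down within cluster 1 (adjusted p = 0.00108). On groups alone it was outside the threshold (adjusted p = 0.435). The erythroid and neutrophil marker lists moved down within cluster 1 too (camera at the preset correlation only, adjusted p = 0.0205 and 0.0496). Day-5 arrays 2 and 3 had erythroid scores of 0.671 and 0.472 and neutrophil scores of 0.364 and 0.489, so other cells in these samples were not excluded.

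Interferon-stimulated genes were lower at day 115 than at day 5 with the cluster term, with 5 of 26 fallen and 1 risen (camera, adjusted p = 0.0485, or 0.522 with an estimated correlation), and within cluster 1 (adjusted p = 0.0114), but outside the threshold on groups alone (adjusted p = 0.172). Isg15 changed by -0.92 (adjusted p = 0.00195) on groups alone. The interferon scores of day-5 arrays were highest in arrays 3 and 4, at 0.497 and 0.281, and ran from -0.131 to 0.187 in the others, and the marker lists that moved within cluster 1 moved in this comparison as well.

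The changes after day 5 could be compared between clusters, which do not share arrays, and both tests were written before their results were seen. Of the 486 calls between day 40 and day 5 in cluster 2, 90.9% had the same sign in cluster 1, 293 of 312 rises and 149 of 174 falls. Of the 112 calls between day 115 and day 5 in cluster 1, 94.6% had the same sign between day 40 and day 5 in cluster 2, 78 of 79 rises and 28 of 33 falls. The differences were smaller in the other arrays. Their median in the direction of the call was 0.713 and then 0.327 (log2) for the first set, and 0.953 and then 0.54 for the second. These values are consistent with changes after day 5 that recur in separate sets of arrays. Whether the change from day 5 to day 40 differed between clusters was tested as an interaction, which gave 0 calls by limma, with 497 at an unadjusted p under 0.05.

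Day 115 against unirradiated hosts was also weighed against the array cluster, since the 2 groups lay wholly in different clusters. If the cluster were the cause, most calls should have the sign of the difference between clusters within day 5, and 92.7% did, which is consistent with a large part of the 2424 calls being due to whatever separates the clusters. A test chosen after the result was seen asked how many stayed called with the cluster as a term, and 274 did. That counts only against a cluster step of equal size in all groups as the whole cause. The step was estimated from day-5 and day-40 arrays, so a step that differed between groups would also leave calls. What separates the clusters is not given in the sources used here, and biology could contribute.

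Random splits of the arrays asked how often other groupings of the same sizes gave as many calls, the real one counted. For day 5 against unirradiated hosts it was 1 of 100 splits, with 55 as the highest other against 69, and with the cluster term 2 of 100, with 215 as the highest other against 138. For day 40 it was 1 of 35, with 0 as the highest other, with and without the term. For day 115 it was 1 of 35, with 2 as the highest other, and 1 of 35 with the term, with 1 as the highest other. This says little, since the real grouping of those 7 arrays was the only split that followed the array clusters. With the term, any cluster difference that it did not remove would still fall mostly on that split. For day 115 against day 5 it was 1 of 100, with 948 as the highest other against 1202, and 1 of 100 with the term, with 364 against 1238.

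Other groupings were as large in the last 2 comparisons. For day 40 against day 5, 6 of 100 splits gave at least the 110 calls, and the highest other, 2595, put 4 cluster-1 arrays in the group of 4 and so followed the clusters. With the cluster term it was 1 of 100, with 576 as the highest other against 646. For day 115 against day 40, 4 of 35 splits gave at least 8 calls, with 268 as the highest other, and 4 of 35 at least 17 with the term, with 212 as the highest other, so chance could have given both counts.

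Eif2s3y, a Y-linked gene, was at 264 and 305 in day-5 arrays 5 and 6 and at 260 and 285 in unirradiated arrays 1 and 2, and under 100 in all others.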
